A study of Coturnix japonica with 42 samples.

How the data were processed

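The mediobasal hypothalamus of male Japanese quail (Coturnix japonica), 8 weeks old, was profiled over 1 short day and the 2 long days that followed. The birds had been kept under 6 h of light and 18 h of dark for 4 weeks and were then moved to 20 h of light and 4 h of dark. Per the labels, 6 birds were taken at each of 21 time points, total RNA was pooled from 3 birds per array, and 2 arrays were made per time point, so that n counts pools and not birds. Biotin-labelled cRNA made from 5 µg of total RNA was hybridised to Affymetrix chicken genome arrays. The probes were designed for chicken, so a dim or unresponsive probe set may reflect sequence that differs in quail.

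The deposited values are signal intensity per probe set on a linear scale, made by the authors with GCOS 1.2. The scaling target and the detection calls are not given in the sources used here. The file held 38535 probe sets on 42 arrays, with values from 0.0239 to 13266.7. The 2% trimmed means of the arrays ran from 25.15 to 40.75, more than the 5% tolerance set for values that share a scale. Each array was therefore multiplied by 1 factor, between 0.796 and 1.29, to bring it to a trimmed mean of 32.42. Values in the text named signal are on that scale.

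The 96 control probe sets were left out, signals under 3.509 were raised to that floor (the median over arrays of the 25th percentile), and log2 was taken. A probe set was kept when its signal was above the median of its array on at least 2 arrays, which left 32057 probe sets. Of the 38439 probe sets that were not controls, 27168 had 1 gene symbol in the platform annotation, 177 had several and 11094 had no symbol. The tested probe sets with 1 symbol numbered 23434 and stood for 12311 genes. Symbols are those of the platform annotation and some may have been replaced since. Where a gene had several probe sets, the brightest over all arrays stood for it. The number of arrays, 2 per time point, limits the precision of every value.

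Time in the labels was read as hours from the start of the short day, with the light coming on at its start. The short day then spans times 2 to 22 h, the first long day 26 to 46 h and the second long day 50 to 70 h, and hour of day is the time within its 24 h day. The labels do not state when the light came on, so statements on which hours were lit rest on that reading. A single model with 1 mean per time point was fitted to all arrays with limma 3.58.1 in R 4.3.3 (21 residual degrees of freedom, empirical Bayes with a variance trend, median prior degrees of freedom 14.81). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, and the threshold was an adjusted p of 0.05. Intervals are 95% intervals from the same model.

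The comparisons were the second long day against the short day over all 6 hours, the first long day against the short day over hours 10 to 22 (as 1 mean and as a joint test of any hour), the same at hours 2 and 6, the second against the first long day, the daily profile of the short day and of the second long day, and the difference of both profiles. Single hours were compared as a breakdown. The short day was not sampled at hours 12, 16 and 20, and for times 36, 40 and 44 h the mean of the neighbouring short-day hours was used. A cosine of 24 h gave the peak hour as a description. Differences named second minus first come from a contrast of their own. All comparisons with the short day share the same short-day arrays, so their results are not independent of each other.

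The text names genes by a fixed rule. It takes members of the lists on thyroid hormone and photoperiod signalling and on the core clock, and the 10 highest and 10 lowest differences past the threshold among genes with 1 symbol and the same sign at all 4 hours, or at 5 or more of 6 hours. For joint tests it takes the 10 smallest p-values. It also takes up to 4 members per list by p. Genes named outside that rule are said to have been chosen after their values were seen. The 20 gene lists were thyroid hormone and photoperiod signalling, core clock, immediate early genes, hypothalamic neuropeptides, anterior pituitary, tanycyte and ependymal cells, oligodendrocyte and myelin, astrocyte, microglia and leukocyte, erythrocyte, choroid plexus, endothelium, neuron, fibroblast and meninges, pineal and photoreceptor, cytosolic heat shock, endoplasmic reticulum chaperones, sterol synthesis, cell cycle, and cold-inducible RNA binding. Each was tested with camera of limma at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. A list of liver genes was added after the data had been seen.

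Array quality was described by the trimmed mean, the median signal, the 3' to 5' ratios of actin and GAPDH, the spike-in controls, the share at the floor and the correlation with other arrays. These were compared between days by a two-sided permutation test with 100000 resamples. The comparisons, the lists, the naming rule and most alternatives were set before the data were examined. The alternatives were quantile scaling, median centring, other floors, other filters, other variance models, the replicate number as a block, other hours, a fit of the compared arrays alone, and leaving out each array in turn. Values as deposited and array brightness as a covariate were added after the data had been seen. On simulated data with the same design, limma found 74% of probe sets shifted by 1 log2 unit between the second long day and the short day, 60% between the first long day and the short day at hours 10 to 22, and 42% at hours 2 and 6. It found 38%, 20% and 11% of those shifted by 0.5. Of the unshifted probe sets it called 8, 9 and 5. The shifted probe sets were drawn from those with a mean above the median. The simulated noise was independent between probe sets and no floor was applied, so the shares need not hold for dimmer probe sets. Correlation between probe sets and genes without a symbol were not analysed further.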

Results

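The 42 arrays covered the mediobasal hypothalamus at 21 time points with 2 arrays each. They fell into 12 arrays of the short day, 18 of the first long day, when times 36, 40 and 44 h were added, and 12 of the second long day. On the deposited scale the 2% trimmed mean per array ran from 25.15 to 40.75. The correlation between both arrays of a time point had a median of 0.895 and was lowest at time 62 h, at 0.812. The design asks which transcripts of this region change when quail are moved from short to long days, and at which hour the change begins.

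During the first long day, transcripts of the thyrotropin subunits and of the enzymes that activate and inactivate thyroid hormone came to differ from the short day. Over hours 10 to 22, TSHB, which encodes the beta subunit of thyrotropin, was 7.13-fold higher than on the short day (95% interval 4.80 to 10.6, n = 8 arrays against 8, limma adjusted p = 1.76e-07, higher at 4 of 4 hours). The size is less certain than the direction, as 4 of 12 short-day arrays lay at the floor and the TSHB difference of 2.83 log2 ran from 1.76 to 3.37 over the alternatives, with the call kept in all 55. CGA, the alpha subunit shared by the glycoprotein hormones, was 2.37-fold higher (interval 1.98 to 2.83, adjusted p = 1.76e-07, 4 of 4 hours). The CGA signal fell within the first long day, from 1350 ± 172 at 34 h to 691 ± 12.8 at 42 h (mean ± SD, n = 2). On the short day it fell further, from 989 ± 45.1 at hour 10 to 160 ± 49.4 at hour 18. DIO2, the deiodinase that makes active thyroid hormone, was 2.05-fold higher (interval 1.63 to 2.59, adjusted p = 7.81e-04). DIO3, the deiodinase that inactivates it, was 3.41-fold lower (adjusted p = 1.02e-06). DIO2 and DIO3 moved in these directions at 3 of 4 hours.

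Hour by hour, TSHB moved before both deiodinases passed the threshold. Its signal was 11.2 ± 6.34 at 36 h and 68.2 ± 0.441 at 38 h (mean ± SD, n = 2), 12.5-fold above the same hour of the short day (limma adjusted p = 0.00562). TSHB was highest at 40 h, at 153 ± 13.8, and was down to 31.7 ± 8.25 at 46 h, still at least 8.89-fold above the short day, where both arrays were at the floor. DIO2 was at 49.3 ± 0.766 at 38 h and 89.7 ± 8.23 at 40 h, and it passed the threshold at 42 h, with a signal of 180 ± 25.7 (3.21-fold, adjusted p = 0.0283). DIO2 reached 235 ± 40.4 at 44 h. DIO3 was at 293 ± 89 at 38 h, 164 ± 16.4 at 40 h and 51.9 ± 15.9 at 42 h, where it was 8.58-fold lower than on the short day (adjusted p = 5.46e-05). DIO3 stood at 31.3 ± 5.45 at 46 h. TSHB passed at 38 h in 49 of 54 alternatives, not without a floor, in the 4 compared arrays alone, or without replicate 1 of 14 h or either array of 38 h. DIO2 and DIO3 passed at 38 or 40 h in 0 of the 54. At 42 h DIO3 passed in 53 of 54 and DIO2 in 45 of 54, where it was lost with median centring, as deposited, without a filter, without a trend, in the compared arrays alone and without single arrays of 18 or 42 h. That these genes changed at different hours was not tested as such.

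EYA3, a transcriptional coactivator and phosphatase, had its highest signals at the hours when TSHB rose, but no test called it. Its brightest probe set read 61.8 ± 4.81 at 38 h and 77.3 ± 3.99 at 40 h, against 18.3 ± 12.4 at 14 h of the short day (mean ± SD, n = 2). The EYA3 difference at 40 h was 4.57-fold with a limma adjusted p of 0.0617, and over hours 10 to 22 it was 1.87-fold (interval 1.32 to 2.67, adjusted p = 0.40). Another EYA3 probe set read 45.4 ± 1.12 at 40 h, and the remaining one 18.8 ± 11.8.

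**Figure D1:**
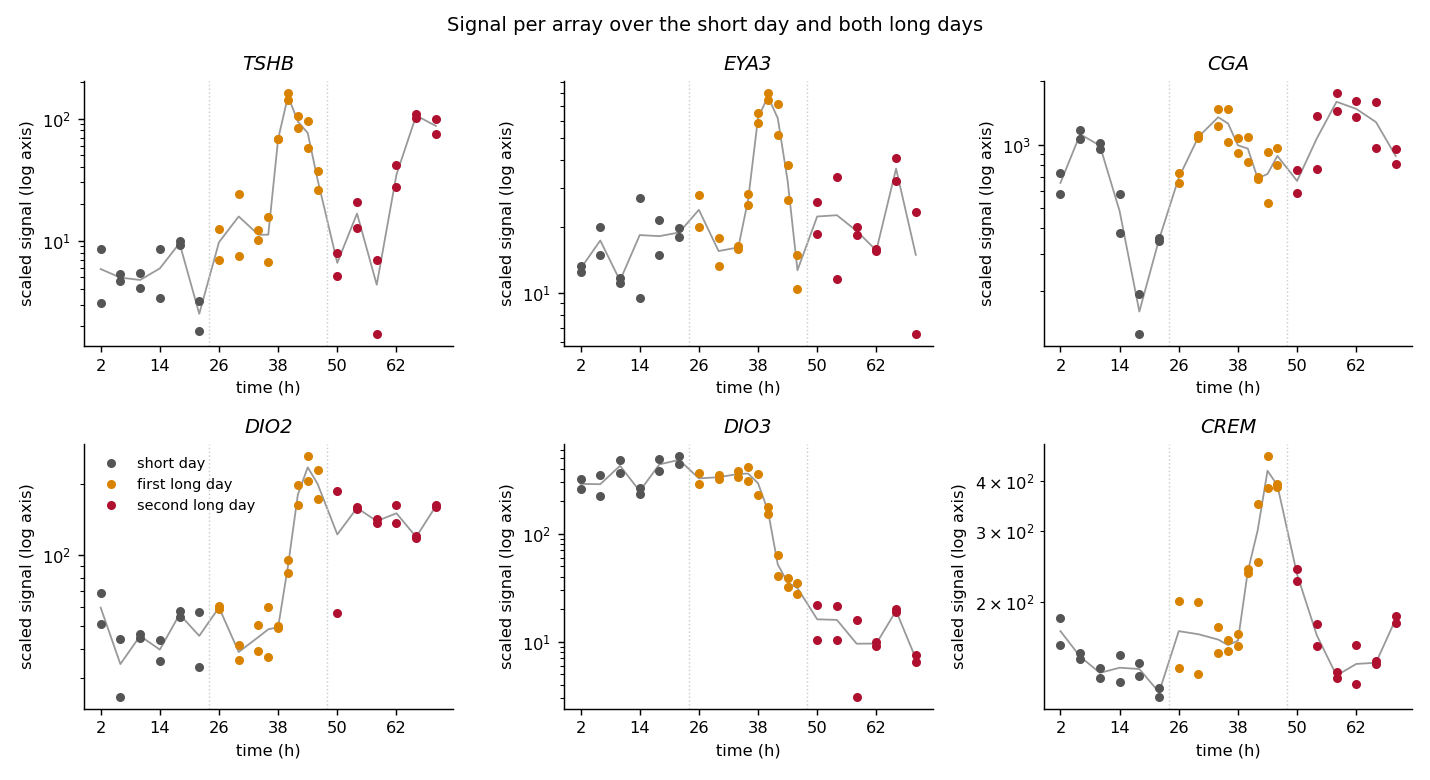
Scaled signal (log axis) of TSHB, EYA3, CGA, DIO2, DIO3 and CREM against time in hours, with 1 point per array coloured by day and a line through the mean of both arrays. TSHB goes from 11.2 at 36 h to 153 at 40 h, and DIO3 from 293 at 38 h to 31.3 at 46 h.

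CREM, EGR1, CRY1 and HSP90B1 were also higher on the first long day than on the short day. CREM, a factor of the cyclic AMP pathway, was 1.78-fold higher over hours 10 to 22 (log2 difference 0.84, SE 0.0946, limma adjusted p = 1.02e-06, 4 of 4 hours). CREM peaked at 424 ± 54.4 at 44 h against 119 ± 4.13 to 136 ± 7.1 at hours 18 and 22 of the short day (mean ± SD, n = 2). EGR1, an immediate early zinc finger factor, was 1.59-fold higher (adjusted p = 7.58e-05). Its single-hour difference passed at 42 h (2.01-fold, adjusted p = 0.0136) and 44 h (2.10-fold, adjusted p = 3.30e-04), in 47 and 51 of 54 alternatives. CRY1, a repressor of the circadian clock, was 1.41-fold higher (adjusted p = 0.00556, 3 of 4 hours). HSP90B1, a chaperone of the endoplasmic reticulum, was 1.53-fold higher (adjusted p = 1.38e-04, 4 of 4 hours). On the short day CRY1 and HSP90B1 were highest at hour 6 and lowest at hour 18, so these differences alone do not show a rise within the first long day.

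In all, 18 probe sets of 15 genes differed over hours 10 to 22 in limma, 12 higher and 6 lower. The joint test of any of these hours called 17 probe sets of 14 genes, led by DIO3, CREM, CGA and TSHB. PCSK7 and LOC427439 were also among the 15 genes and PLSCR1 among the 14, and these 3 were named after their values were seen. DNAJA4 was called on a second probe set (log2 difference 0.74, adjusted p = 0.00556) and not on its brightest one (0.27, adjusted p = 0.822). The other probe sets of DIO2, TTR, CRY1, EGR1 and HSP90B1 were not called. The calls of CRY1 and LBFABP were lost under some alternatives (4 of 55 and 3 of 54 settings, highest adjusted p 0.136 and 0.157). By single hours, 0 probe sets passed in limma at 34 h and at 36 h (1518 and 1505 at an unadjusted p under 0.05). The count was 1 at 38 h, TSHB alone, then 4 at 40 h (TSHB, CGA, CRY1 and FAM219A), 13 at 42 h, 11 at 44 h and 12 at 46 h. These counts rest on 2 arrays per time and ran over the alternatives from 0 to 17 at 34 h, 0 to 20 at 36 h, 0 to 10 at 38 h, 0 to 17 at 40 h, 0 to 38 at 42 h, 1 to 21 at 44 h and 0 to 29 at 46 h, so they do not date the first change. FAM219A at 40 h passed in 34 of 54. FAM219A was named after its values were seen, and so was SOCS3, an inhibitor of cytokine signalling, which was called at 44 h.

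Among the gene lists, the chaperones and the immediate early genes were higher as groups over hours 10 to 22. Of 23 measured endoplasmic reticulum chaperones 20 had positive differences (median log2 0.18, camera adjusted p = 1.64e-08, 0.00352 as adjusted p with an estimated correlation). One of them, HSP90B1, was higher past the threshold over all probe sets, and 5 passed when adjusted over the list alone, with HSPA5 at 0.39 and CRELD2 at 0.41 log2. Of 20 cytosolic heat shock genes 16 had positive differences (median 0.19, adjusted p = 1.32e-05, adjusted p = 0.0321 with an estimated correlation). None of them passed over all probe sets in limma, and 4 passed adjusted over the list alone, with DNAJA1 at 0.28 and HSPA2 at 0.49 log2. Of 22 immediate early genes 15 had positive differences (median 0.12, adjusted p = 1.61e-04, adjusted p = 0.00889 with an estimated correlation). CREM and EGR1 were higher past the threshold among them, and 5 passed adjusted over the list alone, 4 higher and 1 lower. By level, the endoplasmic reticulum chaperones averaged 7.21 and 7.28 log2 at hours 2 and 6 of the short day and 7.03, 6.91, 6.93 and 6.98 at hours 10, 14, 18 and 22, against 7.15 and 7.21 at 26 and 30 h and 7.17, 7.17, 7.14 and 7.11 at 34, 38, 42 and 46 h. The cytosolic heat shock genes averaged 7.77 at hours 2 and 6 of the short day and 7.37, 7.285, 7.45 and 7.41 at hours 10, 14, 18 and 22. On the first long day they averaged 7.82 at 26 and 30 h and 7.64, 7.59, 7.46 and 7.47 at 34, 38, 42 and 46 h.

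The other 3 list calls were lost with an estimated correlation. The core clock list was called higher (19 measured, 1 past the threshold, 1 adjusted over the list alone, adjusted p = 0.0427) with adjusted p = 0.0787 with an estimated correlation. The anterior pituitary list was called higher (13 measured, adjusted p = 0.0427) with adjusted p = 0.0672 with an estimated correlation, and its 2 members past the threshold, also adjusted over the list alone, were TSHB and CGA. The cold-inducible RNA binding list was called lower (8 measured, none past the threshold, adjusted p = 0.0447) with adjusted p = 0.138 with an estimated correlation. The thyroid hormone and photoperiod list was not called (24 measured, adjusted p = 0.275). Of its members TSHB, CGA and DIO2 passed the threshold as higher than on the short day, and DIO3 and TTR as lower. Adjusted over the list alone 6 members passed. The study chose TSHB, EYA3, DIO2 and DIO3 on these samples, so the list is not independent evidence for them. The same holds for TSHB in the anterior pituitary list, which was not tested without TSHB and CGA.

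The other 13 lists were not called over hours 10 to 22, with camera adjusted p from 0.0911 for hypothalamic neuropeptides to 0.781 for sterol synthesis. Over all probe sets the limma threshold was passed by 1 gene of these lists, TTR of the choroid plexus list, and adjusted over the list alone by TTR and by FMOD of the fibroblast and meninges list. No member passed either way among hypothalamic neuropeptides, tanycyte and ependymal cells, oligodendrocyte and myelin, astrocyte, microglia and leukocyte, erythrocyte, endothelium, neuron, pineal and photoreceptor, sterol synthesis, and cell cycle. At the single hour of 42 h, however, NMB of the neuropeptide list was called. NMB was named after its values were seen. The median and the mean of the list differed in sign for choroid plexus (0.07 and -0.09 log2), fibroblast and meninges (0.05 and -0.07), pineal and photoreceptor (-0.02 and 0.03), and erythrocyte (-0.00399 and 0.06).

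**Figure D2:**
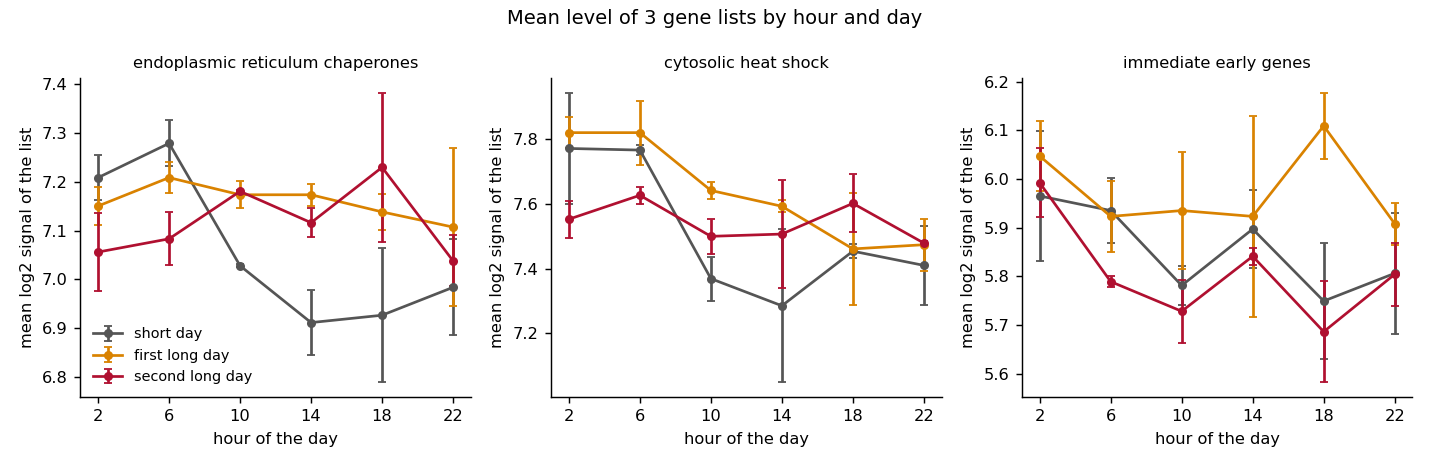
Mean log2 signal of the measured members of 3 lists against hour of day, with lines for the 3 days and bars showing the SD of 2 arrays. On the short day the endoplasmic reticulum chaperones go from 7.28 at hour 6 to 6.91 at hour 14, and on the first long day they stay between 7.11 and 7.21 at these 6 hours.

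ALB, TTR, AvBD9 and LBFABP were lower on the first long day. ALB, serum albumin, was 8.31-fold lower over hours 10 to 22 (log2 difference -3.06, SE 0.322, limma adjusted p = 2.88e-07). TTR, a carrier of thyroid hormone, was 3.66-fold lower (adjusted p = 2.63e-04), and AvBD9, an avian beta-defensin, 4.17-fold lower (adjusted p = 0.00294). LBFABP, a liver fatty acid binding protein, was lower by 2.05 log2 (adjusted p = 0.00294), but 10 of 12 arrays of that day and 3 of 12 of the short day lay at the floor, so the size of its fall is not known, and it ran from -3.46 to -0.66 log2 over the alternatives. All 4 were lower at 4 of 4 hours. ALB was also tested at hours 2 and 6, when the light of both days was the same by the reading of the labels. It read 9.18 ± 1.96 at hours 2 and 6 of the first long day against 44.7 ± 21.1 on the short day (mean ± SD, n = 4), a 4.55-fold difference that did not pass (adjusted p = 0.182).

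**Figure D3:**
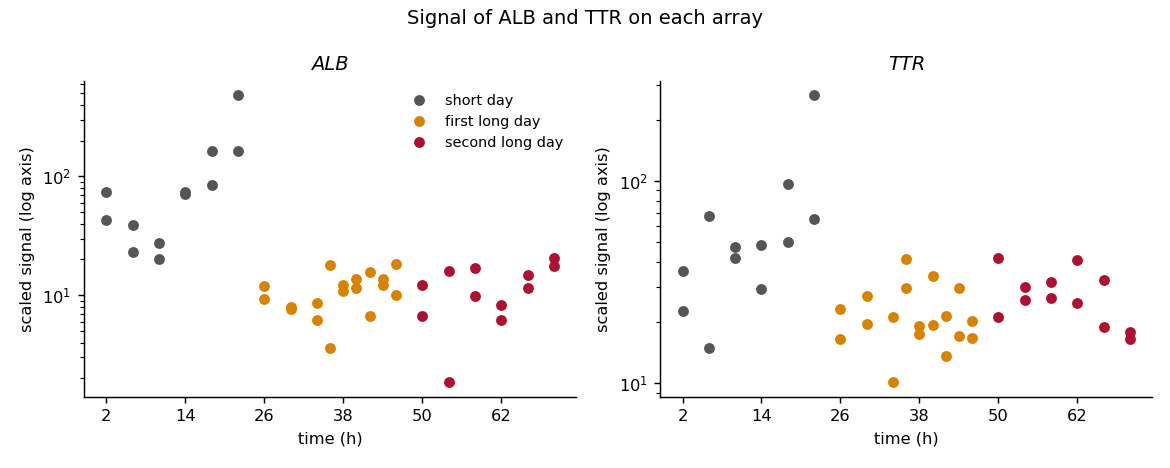
Scaled signal (log axis) of ALB and TTR against time in hours, 1 point per array, coloured by day. For ALB all 12 short-day arrays lie at 20.3 or above, and the highest array of the second long day lies at 20.5.

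At hours 2 and 6, before the light regimes differed, none of DIO2, DIO3, CGA and TSHB passed the threshold. The limma adjusted p was 0.996 for DIO2 and DIO3, 1 for CGA and 0.831 for TSHB (2.13-fold, n = 4 arrays against 4). In simulated data this comparison found 42% of differences of 1 log2 among probe sets with a mean above the median, so differences of that size or smaller can be missed. The simulation applied no floor, where 4 of 12 short-day arrays of TSHB lay, so the share need not hold for TSHB. A single probe set of 32057 was called, LOC427439, named after its values were seen and of no described function here. LOC427439 was 1.71-fold lower (232 ± 25.7 against 402 ± 89, mean ± SD, n = 4, adjusted p = 0.00182). The count at an unadjusted p under 0.05 was 1705. The single LOC427439 call was not made without replicate 1 of time 6 h (0 calls), and the count reached 5 without replicate 2 of time 2 h. None of the 20 lists was called (lowest camera adjusted p 0.666, anterior pituitary), and adjusted over the list alone 1 member of the core clock list passed, lower. The median and the mean of the list differed in sign for neuron and choroid plexus, and the test ran against both for oligodendrocyte and myelin.

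On the second long day DIO3 was lower than on the short day at each hour, and DIO2 was higher on average. DIO3 was 30.5-fold lower than on the short day (12.9 ± 6.40 against 362 ± 106, mean ± SD, n = 12, limma adjusted p = 1.32e-22, lower at 6 of 6 hours). DIO2 was 3.02-fold higher (interval 2.50 to 3.65, adjusted p = 5.77e-10, 6 of 6 hours), with single-hour calls at 54, 62 and 70 h (kept in 51, 50 and 47 of 54 alternatives), and its lowest array of that day (56.9) lay under the highest of the short day (68.6). TSHB was 4.35-fold higher (interval 3.15 to 6.01, adjusted p = 2.27e-07, 6 of 6 hours; 2.12 log2, from 1.35 to 2.70 over the 56 alternatives, all called) and CGA 2.13-fold higher (adjusted p = 1.28e-08, 5 of 6 hours). TSHB was not raised throughout the day, with a signal of 6.59 ± 1.99 at 50 h and 106 ± 5.94 at 66 h (n = 2).

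SOD3, VIM and FAM150B were also higher on the second long day, and ALB and AvBD9 lower. SOD3, the extracellular superoxide dismutase, rose 2.48-fold (133 ± 27.7 against 56.3 ± 23.6, mean ± SD, n = 12, limma adjusted p = 3.04e-07). VIM, the intermediate filament of tanycytes and other glia, rose 1.79-fold (adjusted p = 3.04e-07, 6 of 6 hours), and its signal was 1750 ± 176 at 22 h, 3190 ± 442 at 44 h and 4730 ± 1270 at 54 h (n = 2). FAM150B, a secreted ligand of the receptor kinase ALK, rose 2.23-fold (adjusted p = 7.60e-08). PNPLA3, BLB1, ETV4, SLU7 and SUCLG1 also rose, with short-day means of only 4.95 to 10.5 and 2 to 6 of 12 short-day arrays at the floor, so no fold is given, and each lost its call under some alternatives. ALB fell 6.28-fold (adjusted p = 3.53e-08) and AvBD9 3.06-fold, the latter not called with brightness as a covariate. TNRC18, SIRT1, TTR and DDX19 fell by 1.86 to 2.12-fold, though of 56 alternatives the TTR call was lost in 16, the SIRT1 call in 6 and the TNRC18 call in 2. GREM1, an antagonist of bone morphogenetic proteins (adjusted p = 0.0243), FMOD, a proteoglycan of the extracellular matrix (adjusted p = 0.0288), and CLEC19A (adjusted p = 0.0395) fell to means of 8.98, 3.55 and 4.41, with 3, 8 and 5 of 12 arrays at the floor. Their differences are therefore uncertain in size, from -1.35 to -0.41 log2 over the alternatives for GREM1, -1.53 to -0.17 for FMOD and -1.70 to -0.26 for CLEC19A, and each lost its call under some of them. For BLB1, ETV4, SLU7, SUCLG1, TNRC18, SIRT1, TTR and DDX19 the other probe sets of the gene were not called.

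By list, the second long day moved few groups as a whole. The anterior pituitary list was higher (10 of 13 positive, median 0.32 log2, camera adjusted p = 0.00647, adjusted p = 0.0208 with an estimated correlation), with TSHB and CGA past the threshold, also adjusted over the list alone. TSHB is among the genes the study chose on these samples, and the list was not tested without TSHB and CGA. The thyroid hormone and photoperiod list had 5 of 24 members past the threshold, 3 higher and 2 lower, and 6 adjusted over the list alone (camera adjusted p = 0.172). This list holds the genes the study chose on these samples. Among immediate early genes HOMER1, a scaffold of synapses, fell by 0.44 log2 (adjusted p = 8.95e-04) and EGR1 by 0.38 (adjusted p = 0.00335), and 5 of 22 passed adjusted over the list alone. The HOMER1 call was lost in 1 of 56 alternatives, over hours 10 to 22 alone (highest adjusted p 0.341), and the EGR1 call in 3 of 56, over these hours, without a trend and with brightness as a covariate (highest adjusted p 0.222). In the core clock RORA fell by 0.27 (adjusted p = 0.0338, call lost in 19 of 56 alternatives) and 3 of 19 passed adjusted over the list alone. The endoplasmic reticulum chaperones PDIA3 (0.36, call lost in 4 of 56) and HYOU1 (0.30, lost in 24 of 56, from 0.0311 to 0.328) rose, and 5 of 23 passed adjusted over the list alone. In the cytosolic heat shock list HSPD1 rose (0.55, lost in 4 of 56) and DNAJA4 fell (-0.37, lost in 8 of 56, from -0.63 to -0.0155), and these 2 of 20 passed adjusted over the list alone. The other probe sets of HOMER1, EGR1, RORA, HYOU1, HSPD1 and DNAJA4 were not called. That of HSPD1 stood at -0.0828 and the well-expressed other one of DNAJA4 at 0.159 log2. Another PDIA3 probe set was called (0.545 log2, limma adjusted p = 0.00995).

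The lists of cell types held few changed members on the second long day. VIM was the single one of 21 tanycyte and ependymal genes to pass over all probe sets and adjusted over the list alone. ENPP2 of the myelin and choroid plexus lists rose by 0.29 log2 and SYT1, a synaptic vesicle protein of the neuron list, by 0.27. Over the alternatives ENPP2 ran from 0.0205 to 0.367 log2 and SYT1 from 0.00511 to 0.328. TTR of the choroid plexus list and FMOD and DCN of the fibroblast and meninges list fell. Of these the calls were lost in 43 of 56 alternatives for ENPP2, 41 for SYT1, 25 for DCN and 16 for TTR, and in 15 of 55 for FMOD. Adjusted over the list alone the counts were 1 of 12 for oligodendrocyte and myelin, 3 of 11 for choroid plexus, 1 of 15 for neuron, 3 of 16 for fibroblast and meninges, 2 of 11 for astrocyte, 1 of 25 for hypothalamic neuropeptides (CCK) and 1 of 8 for cold-inducible RNA binding. Microglia and leukocyte, erythrocyte, endothelium, pineal and photoreceptor, sterol synthesis, and cell cycle had no member past the threshold either way. Camera adjusted p for the lists apart from anterior pituitary ran from 0.136 for cold-inducible RNA binding to 0.95. The median and the mean of the list differed in sign for neuropeptides, myelin, neuron and fibroblast.

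In all, 438 probe sets of 344 genes differed between the second long day and the short day in limma, 127 higher and 311 lower, of which 355 kept their sign at 6 of 6 hours. That 29% were higher depends on the scaling between arrays. The split was 145 higher and 246 lower with quantile scaling, 43 and 800 with each array centred on its median, and 48 and 3462 on the deposited values, where the median of all probe sets shifted by -0.18 log2. The arrays of the second long day were dimmer as deposited (trimmed mean 29.0 ± 3.17 against 34.8 ± 3.61, mean ± SD, n = 12, two-sided permutation p = 5.00e-04, adjusted over 14 tests 0.00233). With array brightness as a covariate 150 probe sets were called, and without replicate 1 of time 62 h, which leaves the less typical array of that pair, 746.

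Both long days differed from each other in 29 probe sets of 25 genes in limma, 11 higher and 18 lower on the second. Averaged over all hours, those before the first change included, DIO3 was 14.1-fold lower (adjusted p = 7.93e-19, 6 of 6 hours) and DIO2 1.82-fold higher (adjusted p = 9.40e-04). Over hours 10 to 22 alone DIO2 was not called (0.59 log2, adjusted p = 0.252), and its 235 ± 40.4 at 44 h lay above the highest array of the second long day (187), so no further rise of DIO2 is shown. EGR1 was 1.89-fold lower (928 ± 235 on the first, 484 ± 85.5 on the second, mean ± SD, n = 12, adjusted p = 3.94e-10). FAM150B was 2.10-fold higher (adjusted p = 1.00e-06), SOD3 1.90-fold and VIM higher by 0.59 log2 (both adjusted p = 9.40e-04). CCK, a neuropeptide, was 1.34-fold higher (adjusted p = 0.0424), TF, the iron carrier transferrin, 1.26-fold, CXCR4, a chemokine receptor, 1.32-fold, and TSPAN6, RPL9 and SKP1 1.28 to 1.36-fold. HOMER1, DNAJA4, CREM, DCLK1, ARPP21, ARHGAP24, DDX19 and PKIA were 1.25 to 1.57-fold lower. For all of these 8 but DCLK1, and for DIO2, EGR1, RPL9, TF and CCK, the other probe sets of the gene were not called. Of 55 alternatives the call was lost in 38 for CREM, 37 for SKP1, 36 for DDX19, 26 for CCK, 23 for ARHGAP24, 13 for TF, 9 for PKIA, 4 each for HOMER1, CXCR4 and TSPAN6, 3 for RPL9, 2 each for VIM, DNAJA4 and ARPP21 and 1 for DCLK1. Over hours 10 to 22 alone VIM was not called (0.32 log2, adjusted p = 0.445). TSHB was not called (adjusted p = 0.921, interval 0.66 to 1.26-fold), nor was CGA (adjusted p = 0.513). The split was 5 higher and 66 lower with each array centred on its median and 11 and 934 on the deposited values. Without replicate 1 of time 62 h 142 probe sets were called.

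By list, the immediate early genes EGR1, HOMER1 and CREM were lower on the second than on the first long day (3 of 22, and 4 adjusted over the list alone), with the call lost in 38 of 55 alternatives for CREM, 4 for HOMER1 and 0 for EGR1. The thyroid list had DIO2 and DIO3 (2 of 24, also 2 adjusted over the list alone), and these were among the genes the study chose on these samples. DNAJA4 of the cytosolic heat shock list, CCK of the neuropeptides and VIM of the tanycyte list were the others to pass, with 5 of 20, 3 of 25 and 1 of 21 adjusted over the list alone.

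On the short day CGA, 3 genes of the core clock list and 6 chaperone genes differed between hours. CGA had the smallest p, with a 7.15-fold range between its highest level at hour 6 (1120 ± 78.3) and its lowest at hour 18 (160 ± 49.4, mean ± SD, n = 2, limma adjusted p = 3.24e-08). CRY1 ranged 2.74-fold, highest at hour 6 and lowest at hour 18 (adjusted p = 4.27e-05). NR1D2, a nuclear receptor that represses clock genes, ranged 3.01-fold with its peak at hour 22 (adjusted p = 3.13e-04), and NFIL3, a repressor of the bZIP family, 3.55-fold with its peak at hour 10 (adjusted p = 3.89e-04). ARNTL, the partner of CLOCK, ranged 3.35-fold and did not pass (adjusted p = 0.0783). The chaperone genes BAG3, HSPA2, DNAJA1 and HSPA5 were highest at hour 2 and HSP90B1 and DNAJA4 at hour 6, with ranges of 1.74 to 3.58-fold. HOMER1 ranged 2.38-fold with its peak at hour 2. FAM219A ranged 18.5-fold, highest at hour 14 and lowest at hour 10, where 1 of 2 arrays was at the floor (adjusted p = 0.00173), and its other probe set was not called. ALB, named after its values were seen, ranged 11.9-fold, highest at hour 22 and lowest at hour 10 (adjusted p = 0.0454), and was called in 18 of 54 alternatives. The other probe sets of CRY1, NR1D2, HOMER1, BAG3, DNAJA1 and HSP90B1 were not called. In all, 20 probe sets of 16 genes passed.

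On the second long day the profile of TSHB came first, with a 21.4-fold range, highest at hour 18 and lowest at hour 10, where 1 of 2 arrays was at the floor (limma adjusted p = 1.85e-05). FAM219A, of no described function here, ranged 21.7-fold, having passed on the short day too, and its change of profile was not called (adjusted p = 0.0884). OSMR, a cytokine receptor, ranged 8.86-fold, CCNG2, a cyclin, 6.60-fold and LY75, an endocytic receptor, 4.42-fold. The other probe sets of OSMR, CCNG2 and LY75 were not called (adjusted p from 0.689 to 0.993), and CCNG2 was called in 31 of 54 alternatives. The count was 16 probe sets of 12 genes, and it ran from 10 to 546 with 1 array left out, the highest without replicate 1 of time 62 h. CRY1 (adjusted p = 0.333), NR1D2 (0.358), NFIL3 (0.538) and CGA (0.106) did not pass on that day. The change of profile between both days was tested by itself and called CGA alone (adjusted p = 3.01e-05), which stayed at 1280 ± 452 at hour 18 of the second long day against 160 ± 49.4 on the short day. For TSHB the same test gave an adjusted p of 0.059. The count of 1 rose to 123 without replicate 1 of time 62 h.

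**Figure D4:**
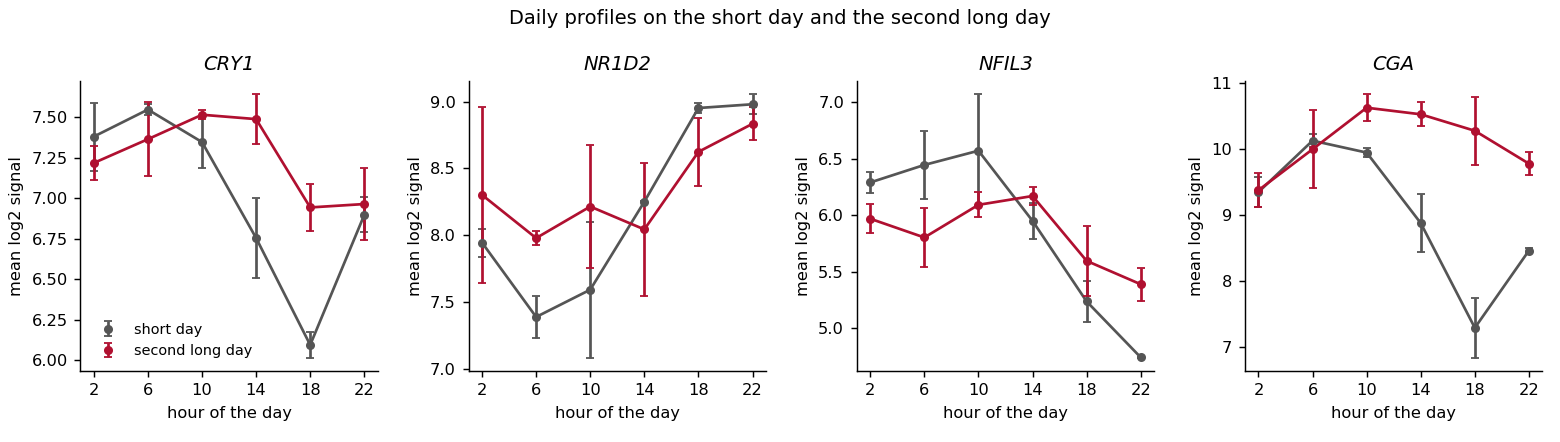
Mean log2 signal of CRY1, NR1D2, NFIL3 and CGA against hour of day on the short day and the second long day, with bars showing the SD of 2 arrays. CGA ranges 7.15-fold on the short day and 2.39-fold on the second long day.

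The arrays differed between days in measures that do not depend on single genes. After scaling, the spike-in controls were 0.20 log2 higher on the second long day than on the short day (two-sided permutation p = 6.00e-05, adjusted 8.40e-04, n = 12 against 12). The dimmer arrays of the second long day (deposited trimmed mean 29.0 against 34.8) were multiplied by larger factors on average. On the log2 scale the factors differed by more than the spike-ins did. The spike-ins were therefore not higher on the second long day before scaling, and this difference came with the scaling. The median correlation of an array with the others was 0.879 ± 0.0217 against 0.895 ± 0.00553 (permutation p = 1.80e-04, adjusted 0.00126), and it was lowest for replicate 2 of time 62 h, at 0.812. The actin 3' to 5' ratio differed by 0.01 log2 (permutation p = 0.854). The first long day had no measure past the threshold against the short day after adjustment over the 14 tests, and 1 of its 7 unadjusted permutation p was under 0.05 (share of probe sets at the floor, 15.3% against 16.1%, permutation p = 0.036).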

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

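The tests of RNA 3' bias, of 1 unusual array, of a day difference present before the light differed and of the chaperone and heat shock levels, by list and together, were chosen only after the result was seen, as were the signal of 20 under which a marker counted as dim and the rule that a list with a share of 0.5 or more dim markers excludes nothing.

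The difference from the short day was not the same on both long days for 29 probe sets, by the test of the second against the first long day itself. Of the genes whose brightest probe set was called, 6 had estimates of opposite sign on both days. These estimates are over all 6 hours, which for the first long day was not among the planned comparisons. An opposite direction is not shown for DNAJA4, RPL9, TF, CCK and SKP1, whose brightest probe sets were not called at hours 10 to 22 of the first long day. EGR1 was 0.54 log2 (SE 0.0752) above the short day on the first long day and at -0.38 (SE 0.0752) on the second, a difference of -0.92 (limma adjusted p = 3.94e-10). Its fall on the second day was not called in 3 of 56 alternatives (from -0.645 to -0.269 log2). These included hours 10 to 22 alone, the hours of its call on the first long day, so an opposite direction at the same hours is not shown. DNAJA4 stood at 0.11 (SE 0.0875) and -0.37 (from -0.63 to -0.0155 log2 over the alternatives), a difference of -0.48 (adjusted p = 0.00766). The other well-expressed DNAJA4 probe set was called on the first long day at hours 10 to 22 (0.74), where the brightest stood at 0.265. It stood at 0.16 on the second long day and was not called between both days (limma adjusted p = 0.258). RPL9 stood at -0.16 and 0.28 (SE 0.076 each), a difference of 0.45 (adjusted p = 0.00273), with an adjusted p of 0.736 on the first long day at hours 10 to 22, and its other well-expressed probe set was not called. TF stood at -0.02 (SE 0.0657) and 0.31, a difference of 0.33 (adjusted p = 0.0204). CCK stood at -0.10 (SE 0.0883) and 0.31, a difference of 0.42 (adjusted p = 0.0424), and SKP1 at -0.02 (SE 0.0763) and 0.34, a difference of 0.35 (adjusted p = 0.0483). The CGA profile differed between the second long day and the short day with an adjusted p of 3.01e-05. Among splits of the arrays within each hour, the real grouping was the only 1 of 100 to give as many calls for the second against the first long day (29 real, highest other 19). That makes chance unlikely for that count. For the change of daily profile 41 of 100 splits, the real one included, gave at least 1 call, with a highest other of 29, so chance cannot be excluded for that count.

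The 438 differences of the second long day came with dimmer arrays and with the least typical array of the series. With array brightness as a covariate the median absolute log2 difference of the called probe sets stayed at 0.987 of its value (0.443 against 0.449, same sign in 438 of 438). The model held 1 mean per time point, so the brightness slope came only from differences between the 2 arrays of a time point. The probe sets had also been called without the covariate. The test therefore cannot exclude a difference between days that came with the dimmer arrays. The count dropped to 150 as the median SE went from 0.0921 to 0.13. A 3' bias is argued against by an actin 3' to 5' difference of 0.0121 log2. Without replicate 2 of time 62 h the median difference of the called probe sets stayed at 0.946 of its value, with the same sign in 438 of 438. That share lay under the 0.97 to 1.04 found without each of the other 23 arrays of both days. The probe sets had been called with that array included, and it is 1 of the 12 arrays of its day. A large loss was therefore unlikely in advance, and the test cannot decide how far that array contributed to the calls. The 196 probe sets called on hours 10 to 22 alone were shifted at hours 2 and 6 of the first long day by 0.248 of their later shift (0.143 against 0.574, in the called direction for 152). A day difference that preceded the light thus cannot be told apart from a response to light for part of the calls. This check covers the first long day only. No short-day arrays were made for the second long day, so a difference particular to that day cannot be told apart from light for any of the 438. The real grouping was the only 1 of 100 splits to give as many calls (438 real, highest other 145), which makes chance unlikely for that count.

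ALB, TTR, LBFABP and AvBD9 were higher on the short day than on the long days. For choroid plexus in the short-day pools the other 10 genes of that list had a median difference of -0.134 log2 (bootstrap interval -0.274 to 0.00516). This lay under the bound set before the test was run, though after the pattern had been seen. Of the 10 genes 5 had a short-day signal under 20, and ENPP2 (687 ± 93.4) and AQP1 (136 ± 38.9), the brightest, are high on all days. For RNA from liver the other 26 liver genes had a median of 0.022 log2 (bootstrap interval -0.053 to 0.223). This too lay under a bound set before the test was run, but the liver list was added after the data had been seen. Of the 26 genes 20 had a short-day signal under 20, and APOH (970 ± 141) and VTN (259 ± 40.7), the brightest, are high on all days too. The 26 ran from -0.665 (RBP4) to 0.826 (FGG) log2, with FABP1 at 0.598, and none passed (lowest adjusted p 0.252). Both bootstrap intervals come from resampling genes and not arrays, so they leave out the spread between pools. Neither bound was able to exclude a small share of such RNA, so choroid plexus and liver cannot be told apart from a change within the tissue.

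The endoplasmic reticulum chaperone and heat shock genes were higher at hours 10 to 22 of the first long day. Over the 43 members of both lists, these hours stood at a median of -0.108 log2 from hours 2 and 6 of the short day (interquartile range of members 0.354), which does not decide for both lists together whether the fall of the short-day night was missing. For the 23 endoplasmic reticulum chaperones the change from hours 2 and 6 to hours 10 to 22 within the first long day was 0.0607 of that within the short day (medians -0.0109 and -0.179 log2, bootstrap interval of the share -0.285 to 0.376). These may have missed the fall of the short-day night under extended light rather than been induced above their daytime level, a hypothesis found and tested on the same arrays. By the reading of the labels the light had ended before hour 22. The share also leaves out 36, 40 and 44 h, with list means of 7.17, 7.293 and 7.169 log2 (SD 0.163 at 40 h, n = 2). The mean at 40 h lay slightly above the 7.278 at hour 6 of the short day, so a rise at that hour is not excluded. The 20 cytosolic heat shock genes fell within the first long day as well (median -0.196 log2 against -0.301, a share of 0.651, bootstrap interval 0.347 to 1.73; list mean -0.279, SE 0.0642), which argues against a missing fall for them. The bootstrap resampled the genes of a list and not the arrays, so its intervals leave out the spread between pools. The SE of the list mean comes from the arrays. No technical explanation was tested for this pattern.

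Among the remaining counts, the real grouping was the only 1 of 100 splits to give as many calls for the first long day at hours 10 to 22 (18 real, highest other 11). It was the only 1 of 81 for the joint test (17 real, highest other 14). Chance is unlikely for both, though the highest other counts came near the real ones. For hours 2 and 6 the 18 splits are too few for a share under 0.05, with a real count of 1 and a highest other of 1 (4 of 18 splits gave as many, the real one included).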

How the results depend on the processing

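Values as deposited and array brightness as a covariate were chosen only after the result was seen. Every other alternative was planned. No named difference of means past the threshold and no called list changed its direction under any alternative run. Joint and profile tests have no direction. The median shift of all probe sets between the second long day and the short day did change sign. It was 0.0423 log2 in the main fit, -0.00528 with quantile scaling and -0.0822 with median centring. Of the 8 counts and the list tests, the first long day at hours 10 to 22 (18) stayed within 1.5 times its value under all 13 other settings and all 42 fits with 1 array left out. Where a cause is not named it was not tested.

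For the second long day against the short day (438) the count was 843 with each array centred on its median, 3510 as deposited, 149 without a variance trend, 196 over hours 10 to 22 alone, 272 in a fit of the compared arrays (fewer degrees of freedom) and 150 with brightness as a covariate. For the second against the first long day (29) it was 71 with median centring, 58 with the floor at the 50th percentile, 945 as deposited, 9 without trend and 12 over hours 10 to 22. The joint test of the first long day (17) gave 41 with the higher floor, 10 without trend and 11 in the compared arrays. Hours 2 and 6 (1) gave 2 with quantile scaling, 9 with the higher floor, 2 without a filter, 14 as deposited, and 0 without trend and in the compared arrays. The short-day profile (20) gave 57 with the higher floor and 3 in the compared arrays. The profile of the second long day (16) gave 37 without a floor, 348 with the higher floor, 115 without a filter, 10 as deposited, 33 without trend and 2 in the compared arrays. The change of profile (1) gave 5 with quantile scaling, 4 without a floor, 2 with the floor added, 98 with the higher floor, 20 without a filter, 3 with a filter on the mean, 9 without trend and 4 with a robust trend. The list tests (7 calls) gave 4 with an estimated correlation and 4 with the mean over the probe sets of a gene. The replicate block gave 432 for the second long day, 18 for the first, 30 between both, 21 and 19 for the profiles and 1 for their change.

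With each array left out in turn, counts ran from 313 to 746 for the second long day, 15 to 24 for the first, 14 to 24 for its joint test, 0 to 5 at hours 2 and 6, 20 to 142 between both long days, 18 to 28 for the short-day profile, 10 to 546 for the profile of the second long day and 1 to 123 for the change of profile. The array left alone at its time point was assumed to vary like the others. The highest counts of 746, 142, 546 and 123 came without replicate 1 of time 62 h, which leaves the least typical array alone. At hours 2 and 6 the arrays that moved the count by over 1.5 times were both of times 2, 18, 26, 30, 50 and 54 h (2 to 5 calls) and replicate 1 of time 6 h (0). For the profile of the second long day they were both of times 2, 38, 44 and 46 h (10), both of times 50, 54 and 66 h, and replicate 1 of times 58 and 62 h (26 to 546). The change of profile moved without 20 of the 42 arrays. Counts at single hours of the first long day had a lowest value of 0 or 1 and a highest of 8 to 38.

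Of 63 named differences 23 passed under every alternative run. The least firm were ENPP2 (weaker in 43 of 56 settings), SYT1 (41), SLU7 (31), DCN and CLEC19A (25 each) for the second long day, and CREM (38 of 55), SKP1 (37), DDX19 (36) and CCK (26) between both long days. For the second long day the call was also lost in 24 settings for HYOU1, 21 for ETV4, 19 for RORA, 16 for TTR, 15 for FMOD, 13 for GREM1, 10 for BLB1, 9 for PNPLA3, 8 for DNAJA4 and 6 for SIRT1. Between both long days it was lost in 23 for ARHGAP24, 13 for TF and 9 for PKIA. ENPP2 and SYT1 each had another probe set called for the second long day (0.60 log2, limma adjusted p = 4.56e-04, and 0.43, adjusted p = 0.0411). Over the alternatives LBFABP ran from -3.46 to -0.66 log2 on the first long day and lost its call in 3 of 54 settings.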

Other observations

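The following values were looked at only after the named results had been seen, and no further tests were chosen for them.

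No hypothalamic neuropeptide passed the threshold over all probe sets between the second long day and the short day, and adjusted over the list alone CCK did. CCK read 271 ± 74.8 at 66 h and 262 ± 37.4 at 70 h against 196 ± 51.8 and 150 ± 35.7 at the same hours of the short day (mean ± SD, n = 2), and its limma adjusted p was 0.0662 over all probe sets. Of 25 measured neuropeptide genes 9 had positive differences, with a median of -0.03 log2.

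VIM and FAM150B had their highest signals on the second long day. VIM read 1840 ± 680 at 42 h and 3460 ± 444 at 46 h, and FAM150B 54.4 ± 4.88 at 46 h and 138 ± 6.04 at 54 h (mean ± SD, n = 2). SOD3 read 91.7 ± 14.0 at 46 h and 161 ± 25 at 58 h. Their timing was not tested.

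LOC427439 read 472 ± 60.0 at 2 h, 332 ± 24.5 at 6 h, 293 ± 9.17 at 22 h, 215 ± 13.8 at 26 h and 192 ± 13.0 at 70 h (mean ± SD, n = 2).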
